A study of Pseudomonas putida with 2 samples.

How the data were processed

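The series measured the transcripts of the bacterium Pseudomonas putida, isolate NBAII-RPF 9, on 1-colour Agilent microarrays labelled with the dye Cy3. There were 1 control array and 1 heat array. Per the labels' protocols, a pair of flasks of Luria Bertani broth was grown from the same starter, and the heat culture was then held at 45 °C for 1 h. Total RNA was purified on columns and labelled as cRNA. The labels give the growth stage in 3 ways (a 24 h culture, an exponential culture and an overnight culture), and this was not settled here. The letter N in the control title is not explained by the labels, and the control group was taken from the source description. Both arrays lay on 1 slide, so slide does not separate the groups.

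The authors deposited, for each probe and array, a processed signal, which is an intensity on a linear scale. Per the file headers it was dye-normalised and background-subtracted, and per the submitters' processing notes it came from Agilent Feature Extraction 9.1. The authors also deposited a detection flag in words (detected or compromised) for each probe and array. A deposited log2 fold of heat over control accompanies them. That log2 fold equalled the log2 ratio of the signals minus 0.97 for every probe (range of the constant over probes 2.32e-06), and the constant of the 75th percentiles computed here was also 0.97. The value table of the series holds the same intensity values as deposited, rounded to within 0.005. It leaves out 152 probes, which are exactly those at 1000 or more on either array, and 2 of its probes have no annotation here and were not used.

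The complete table has 5334 probes of 45 to 60 bases for 5294 genes, of which 1468 carry a gene symbol. Positions are those of the P. putida KT2440 chromosome, on which the probes were designed. Gene names and products were taken from that table. The reference gene table belongs to another strain and was not used. A total of 140 probes are marked as cross-hybridising, meaning that they bind more than 1 gene, and for some of them the printed product is that of the other gene. The deposited tables hold 1 value per probe, no saturation flag, and no separate mean and background signals.

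The main setting was log2 of the processed signal minus log2 of each array's 75th percentile over all probes. A gene was kept when a probe of it was detected on both arrays, its value was the mean over such probes, and the reported quantity is the log2 difference, heat minus control. Fewer than 50% of the probes were detected on the control array, for which a percentile over detected probes is an option. The all-probe percentile was kept because it had been fixed before the data were examined, and the other was run as an alternative. A gene counted as higher or lower at a difference of 2-fold (1 on the log2 scale) or more. Genes detected on 1 array alone were given as "at least N-fold", the bright signal against the higher of the dim probe's own signal and the lowest detected signal of the dim array, after scaling.

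With 1 array per group there are no replicates, no test was run between the groups, and no p-value or error between cultures can be given. The number of arrays limits the precision. The only error these arrays give is the agreement of different probes of 1 gene. Over 15 genes with a pair of probes detected on both arrays, the SD of 1 probe was 0.756 on the log2 scale. The pair of mexD, which includes a cross-hybridising probe, differed most, by 3.05, and weighed heavily on that SD. The median absolute difference within a pair was 0.28, 12 pairs lay within 1 log2 unit, and 3 pairs lay on opposite sides of 0. This error is technical and leaves out the spread between cultures.

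Before the data were examined, 23 gene lists were fixed, 21 by gene symbols and 2 by product words (phage-related, and transposases and integrases). A gene without a symbol joined a list when its product contained a listed symbol as a whole word in any case. That rule was kept as fixed, although it matches loosely. In the osmoprotection list the symbol betA matched the word beta in 20 products, 11 of them of kept genes, which are not osmoprotection genes. The general stress list holds rsmA, here a dimethyladenosine transferase, and the heat shock list holds PP_3970, an alcohol dehydrogenase. Values by symbol alone are given in the text for the lists this affects. For each list with 3 or more kept genes, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean signal in 10 bins. That percentile describes these 2 arrays. A list stood apart when it lay outside the middle 95% of the random lists.

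The genes named were chosen by a rule fixed before the data were examined. They are the 12 largest differences in each direction among genes with a symbol or a product of known function, whose probes lay on the same side of 0; the kept members of the heat shock list; the 2 highest and 2 lowest members of each other list; and up to 6 genes per direction detected on 1 array alone. Other genes are marked as chosen after their values were seen, apart from list members not detected on both arrays and neighbours used in a test.

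The 2-fold threshold was tested on simulated log2 differences for the heat against control comparison, with 2144 genes of which 200 were shifted. Array signals, the scaling and the detection filter were not simulated. With the probe SD of 0.756 as noise, 84% of genes raised by 1.5 log2 units and 78% of those lowered by 1.5 passed the 2-fold threshold, and 18.2% of unshifted genes passed it too. With a median-based SD of 0.29, 98% passed and 0.051% of unshifted genes did. Of random lists raised by 1 log2 unit, 50% of those with 5 genes, 90% with 13 and 99% with 30 were placed above the middle 95%.

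The alternatives concerned the scaling, the filter, the way probes of a gene are combined, the fold threshold, the matching of random lists and the matching of list members. Alternatives chosen after seeing the data were the percentile over detected probes, the value table of the series, leaving out cross-hybridising probes, numbered gene copies as list members, leaving out 4 genes over 100-fold apart when undetected signals are taken at face value, removal of a trend on probe composition and signal, and protein names in place of products for genes with cross-hybridising probes alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.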

Results

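Transcript levels were compared between a P. putida culture held at 45 °C for 1 h and its untreated control, with 1 array for each. On the control array 2267 of 5334 probes were detected (42.5%), with a median signal of 3.09 and a 75th percentile of 15.3. On the heat array 2897 were detected (54.3%), with a median signal of 8.77 and a 75th percentile of 29.9. Both arrays detected 2159 probes, the control array alone 108, the heat array alone 738, and neither 2329. There are no replicates, so every difference below describes these 2 arrays. The only error available is that between probes of 1 gene, with an SD of 0.756 on the log2 scale for 1 probe.

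The comparison asks which transcripts differ after heat shock. Chaperone and protease genes were among the most strongly higher genes on the heat array, and the list medians of ribosomal protein and respiratory chain genes were lower, though not every such gene was. Of 2144 genes detected on both arrays, 264 (12.3%) were at least 2-fold higher on the heat array, 429 (20.0%) were at least 2-fold lower, and 1451 lay within 2-fold. In the simulation 18.2% of unshifted genes passed 2-fold with the probe SD of 0.756 as noise, and 0.051% with the median-based SD of 0.29. Part of these counts can therefore be technical. In the main setting the higher genes reached further, with 105 at least 4-fold higher against 42 at least 4-fold lower, and 40 at least 8-fold higher against 2 at least 8-fold lower. Those 4-fold and 8-fold counts were taken in that setting alone and depend on the scaling too. Across genes the log2 signals of the arrays correlated with Pearson's r of 0.864 and Spearman's rho of 0.854, where genes are not independent replicates. The balance between the directions depended on the scaling, the filter and the threshold. It was 264 higher against 429 lower in the main setting (38.1% higher), 159 against 882 when each array was scaled to its median (15.3%), 813 against 48 without scaling (94.4%), and 351 against 263 after loess (57.2%). It was 687 against 536 with genes detected on at least 1 array (56.2%) and 151 against 127 at 3-fold (54.3%). The median gene differed by -0.26, and the array medians, no scaling and loess moved it by -0.54, 0.97 and 0.18. List medians are therefore also given relative to the median gene.

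**Figure D1:**
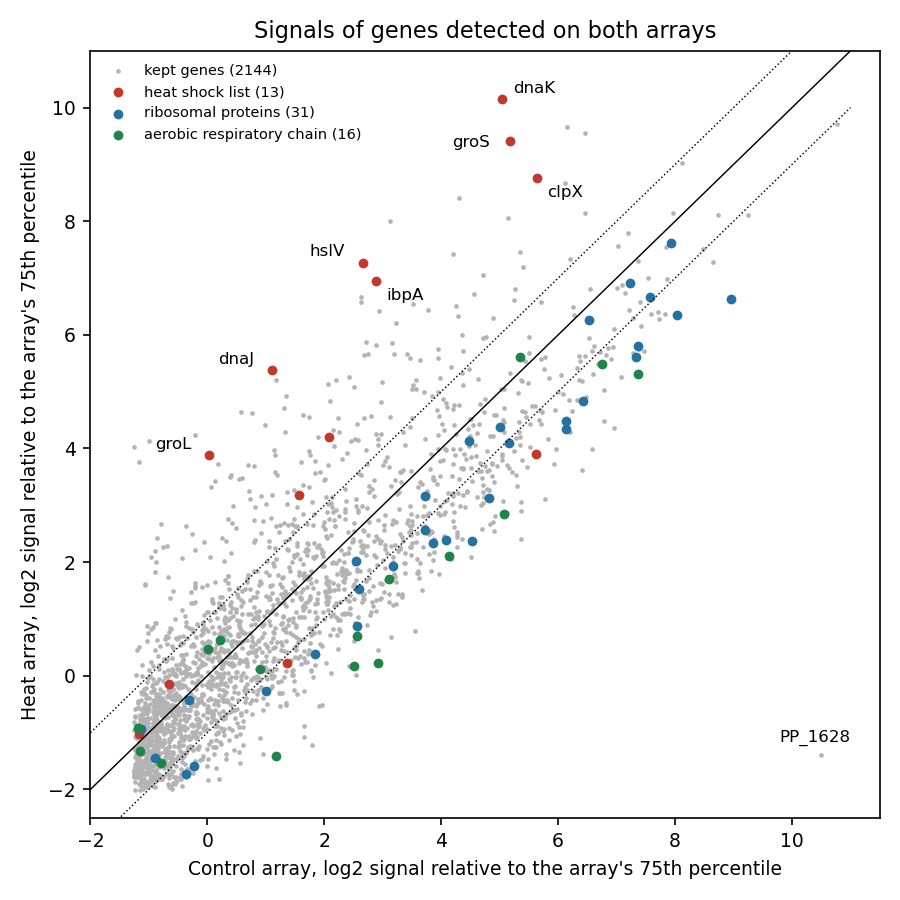
Each point is 1 of 2144 genes detected on both arrays, with its log2 signal relative to the array's 75th percentile on the control array (x axis) and the heat array (y axis); the solid line marks equal values and the dotted lines a 2-fold difference. The heat shock genes dnaK, groS, clpX, hslV, ibpA, dnaJ and groL lie above the upper dotted line, while most ribosomal and respiratory chain genes lie below the solid line.

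The cytosolic heat shock list, which holds chaperones that fold or rescue proteins and proteases that degrade them, stood furthest apart. Of its 25 genes on the array, 13 were detected on both arrays, 9 of these were at least 2-fold higher after heat and 2 at least 2-fold lower. Their median log2 difference was 3.13 (8.73-fold), or 3.39 relative to the median gene, above all 10000 random lists. The highest was dnaK (PP_4727, positions 5375637 to 5377562 on the minus strand), the Hsp70 chaperone, whose signal was 503.8 in the control and 33901 after heat, 34.4-fold higher after scaling and the brightest signal of the heat array. Its co-chaperone gene dnaJ was 19.3-fold higher, measured by a probe that also binds the related gene cbpA. The chaperonin genes groS (PP_1360) and groL (PP_1361) were 18.9-fold and 14.4-fold higher, and the small heat shock protein gene ibpA (PP_1982) was 16.7-fold higher. Among the proteases, hslV, the peptidase subunit of HslVU, was 24.4-fold higher, clpX, the ATPase subunit of ClpXP, 8.73-fold higher, and the membrane protease gene ftsH 3.04-fold higher. The chaperone gene hscA was 4.32-fold higher.

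Not every member of that list was higher. The log2 difference was 0.52 for hslR and 0.15 for PP_4849, a putative DnaK protein, and with each array scaled to its median these values were -0.017 and -0.39. The protease gene htpX was 2.20-fold lower, and PP_3045, a putative ClpP protease beside a phage portal protein gene, was 3.30-fold lower. The genes hslU, hslO, clpB, hscB, htpG and PP_3970 were detected on the heat array alone. For hslU, the ATPase subunit of HslVU, this means at least 13.8-fold higher. The nucleotide exchange factor gene grpE was detected on the control array alone, at least 1.83-fold lower after heat in the main setting. Its control signal was 6.95, near the lowest detected one of 6.37, and without scaling its bound sets no direction. The genes clpP, clpA, clpS, cbpA and rpoH, the gene of the heat shock sigma factor, were detected on neither array. The list's median was above 0 under every scaling tried, from 2.59 with array medians to 4.09 without scaling. In the value table of the series, which lacks the brightest probes, it was 0.79 relative to the median gene, at the 94.8th percentile.

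**Figure D2:**
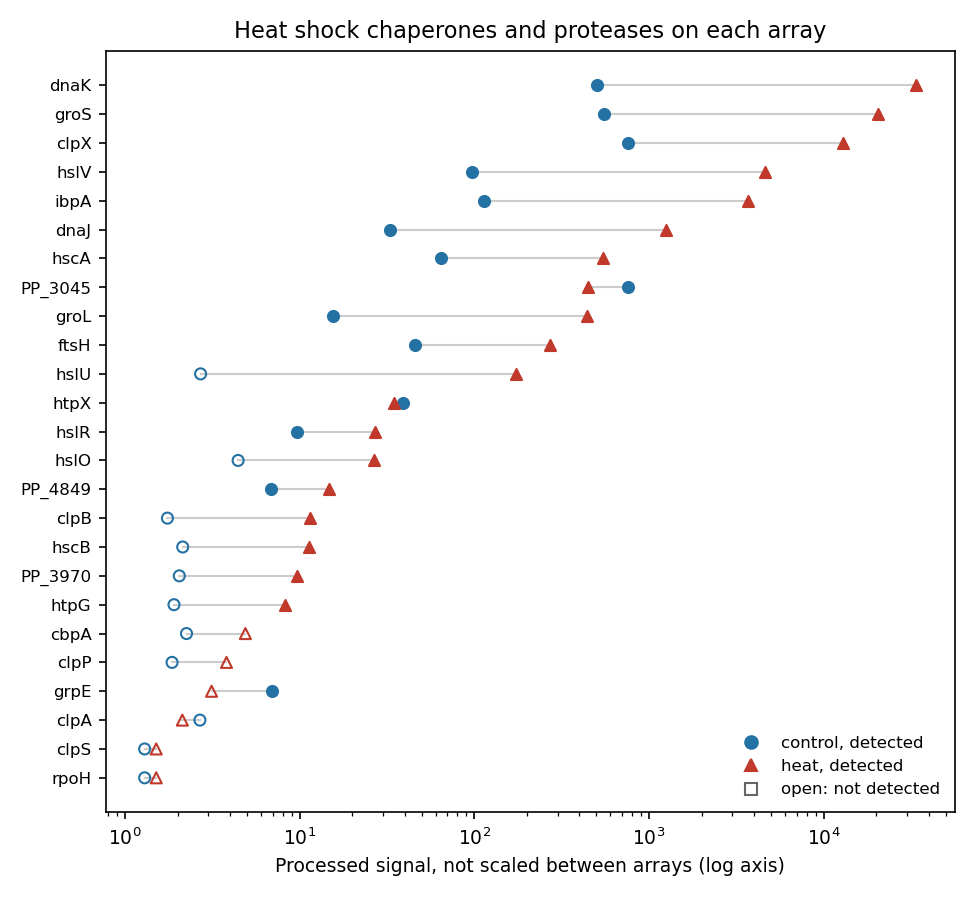
Processed signals on a log axis, not scaled between arrays, of the 25 genes of the heat shock list, with circles for the control array and triangles for the heat array; open symbols are not detected. The signal of dnaK is 503.8 on the control array and 33901 on the heat array, while clpP, clpA, clpS, cbpA and rpoH are detected on neither.

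The list of ribosomal protein genes had a lower median. Of 53 on the array, 31 were detected on both arrays, and 20 of these were at least 2-fold lower and 0 at least 2-fold higher. Their median was -1.27 (2.42-fold lower), or -1.01 relative to the median gene, below all 10000 random lists. The lowest were rpmI (50S protein L35, PP_2467), 4.98-fold lower with signals of 7586 and 2977, and rpsJ (30S protein S10, PP_0453), 4.44-fold lower. The highest of them, rpsP, had a log2 difference of 0.18. Another 8 were detected on the heat array alone, of which rplV, rplA and rplC were at least 1.42-fold, 1.14-fold and 1.11-fold higher and 5 had bounds that set no direction. With array medians none of the 8 bounds sets one. The gene rpsC was detected on the control array alone, at least 2.37-fold lower after heat, and 13 were detected on neither. The median stayed below 0 under every scaling, from -1.81 with array medians to -0.30 without scaling. Without the filter on dim probes it was -0.28 relative to the median gene, at the 2.85th percentile.

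The aerobic respiratory chain list, which holds NADH dehydrogenase, the cytochrome bc1 complex, quinol oxidases and ccoS, had a median lower by a similar amount. The fixed list leaves out other oxidase genes. Of these PP_0104 and PP_0103 were 16.7-fold and 3.20-fold higher, and PP_0106, in the same region, was at -0.15. Of the numbered cbb3-type genes, ccoP-1, ccoN-1 and ccoN-2 were 8.04-fold, 7.74-fold and 6.94-fold lower. The cbb3-type genes ccoO-1, ccoQ-1 and ccoO-2 had log2 differences of 0.55, 0.11 and -0.42. Of the genes left out, PP_0103, PP_0106, ccoO-1, ccoQ-1 and ccoO-2 were chosen after their values were seen. Of the 23 list genes on the array, 16 were detected on both arrays and 7 on neither. Of the 16, 9 were at least 2-fold lower and 0 at least 2-fold higher. The median was -1.33 (2.52-fold lower), or -1.07 relative to the median gene, below all 10000 random lists. The NADH dehydrogenase genes nuoC (PP_4121) and nuoN (PP_4131) were 6.45-fold and 5.98-fold lower. In all 4 genes lay above 0, the highest being the quinol oxidase genes cyoB and cioB at 0.47 and 0.41. The median stayed below 0 under every scaling, from -1.87 with array medians to -0.37 without scaling. Without the filter on dim probes it was -0.34 relative to the median gene, at the 0.965th percentile.

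**Figure D3:**
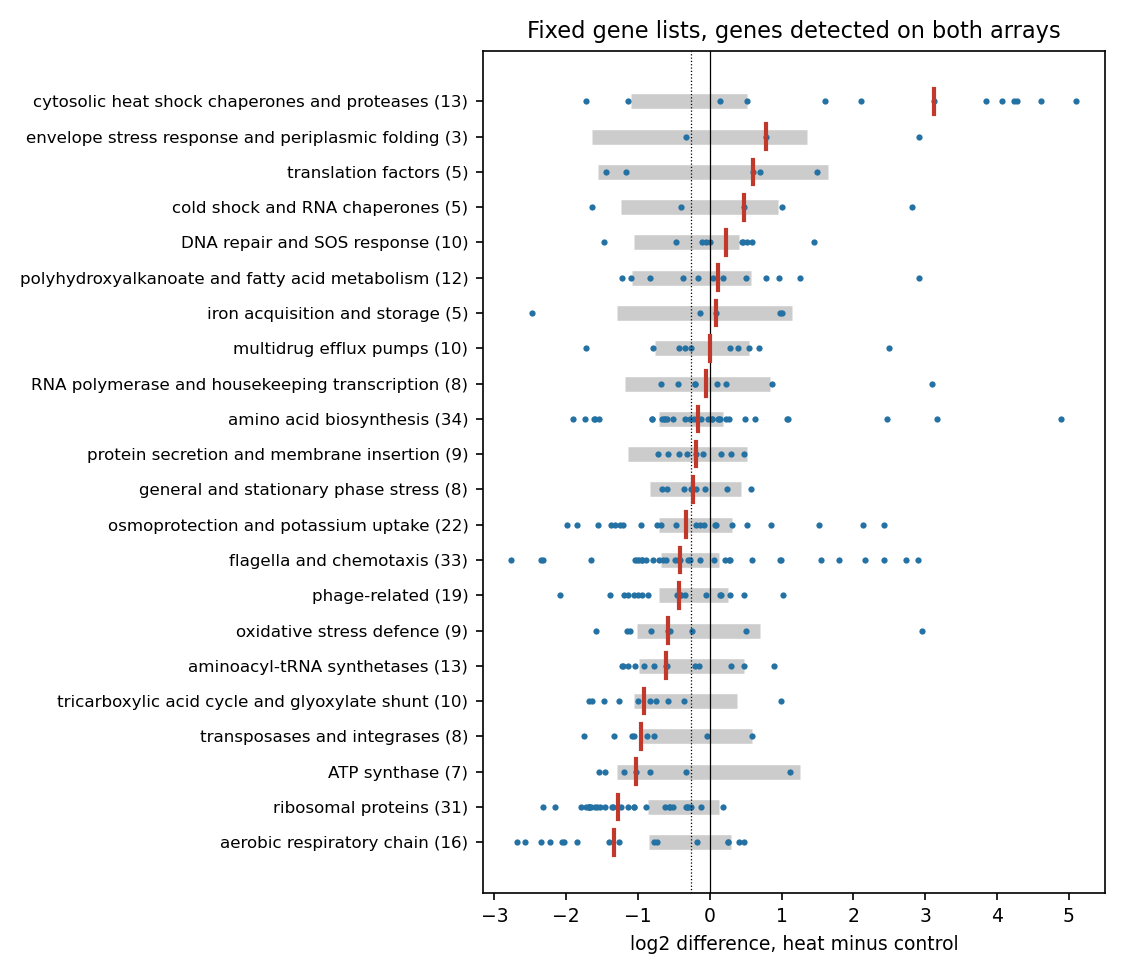
Log2 differences, heat minus control, of the kept genes of 22 fixed lists (points), with each list's median in red and the number of kept genes in brackets; grey bars span the middle 95% of medians of random lists matched on size and signal, the solid line is 0 and the dotted line the median gene. The heat shock median of 3.13 lies right of its bar, and the ribosomal and respiratory chain medians of -1.27 and -1.33 lie left of theirs.

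The other 19 lists lay within the middle 95% of random lists, and their medians are given relative to the median gene. Among lists of energy metabolism, the tricarboxylic acid cycle and glyoxylate shunt list was at -0.65 (10 genes, 7.39th percentile), with the succinate dehydrogenase genes sdhA and sdhB 3.20-fold and 3.12-fold lower. The ATP synthase list was at -0.77 (7 genes, 13.8th percentile), with atpE and atpG 2.93-fold and 2.76-fold lower and atpI 2.16-fold higher. Transposases and integrases were at -0.70 (8 genes, 2.98th percentile), with PP_4420 3.36-fold lower, and phage-related genes at -0.17 (19 genes, 24.8th percentile), with the pyocin tail gene gpD 4.26-fold lower and PP_3870 2.02-fold higher.

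Among the other lists of gene expression, aminoacyl-tRNA synthetases were at -0.34 (13 genes, 20.8th percentile), with cysS 2.35-fold lower. Translation factors were at 0.86 (5 genes, 87.7th percentile). There the elongation factor G genes fusA and fusB were 2.72-fold and 2.25-fold lower, each measured by a cross-hybridising probe alone, so these need not be separate measurements. The specific probe of fusB was detected on neither array. In the same list PP_5044 (TypA) was 2.81-fold higher, and by symbol alone the list was at -0.022. The RNA polymerase list was at 0.21 (8 genes, 69.6th percentile). In it rpoD, the housekeeping sigma factor gene, was 8.57-fold higher, with signals of 1343 and 22515, whereas rpoA, the gene of the alpha subunit, was detected on the control array alone, at least 16.9-fold lower after heat. Cold shock and RNA chaperone genes were at 0.74 (5 genes, 91.8th percentile), with hfq 7.02-fold higher and rhlB 3.13-fold lower.

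Among stress lists, envelope stress was at 1.04 (3 genes, 93.4th percentile), with mucA, the gene of an anti-sigma factor, 7.56-fold higher. Without the filter on dim probes this list was at -0.11 (38.5th percentile), and with detection on at least 1 array at 0.15 (74.7th percentile). The fixed list leaves out algT (sigma factor AlgU) and algY (a Do-type protease), which carry other symbols and were chosen after their values were seen. The gene algT was detected on the heat array alone, at least 1.73-fold higher, and algY was 9.79-fold higher. Oxidative stress defence was at -0.32 (9 genes, 20.8th percentile). Its glutathione synthesis gene gshA was 7.73-fold higher, and the superoxide dismutase genes sodB and sodA were 3.01-fold and 2.22-fold lower. General and stationary phase stress was at 0.032 (8 genes, 39.8th percentile), with 0 genes past 2-fold. DNA repair was at 0.48 (10 genes, 93.5th percentile), with uvrC 2.73-fold higher and recA 2.79-fold lower. Osmoprotection and potassium uptake was at -0.072 (22 genes, 32.8th percentile) and, without the members matched by product words, at 0.45 (10 genes, 88.9th percentile). Its glycine betaine synthesis genes betA and betB were 5.38-fold and 4.36-fold higher, and kdpC, of a potassium pump, was 3.95-fold lower.

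Flagella and chemotaxis was at -0.15 (33 genes, 27.0th percentile), with 6 genes at least 2-fold higher and 6 lower. Of these motB (PP_4335), whose printed product is MotD, was 7.44-fold higher, and flgH and flgG, of the basal body, were 6.80-fold and 5.09-fold lower. PP_4904, whose printed product is MotB, was not detected on both arrays. Amino acid biosynthesis was at 0.10 (34 genes, 72.6th percentile), with dapB and cysE 29.5-fold and 8.99-fold higher and glnA 3.75-fold lower. Polyhydroxyalkanoate and fatty acid metabolism was at 0.37 (12 genes, 84.0th percentile), with accB and accD 7.56-fold and 2.38-fold higher and fadD and phaC 2.32-fold and 2.13-fold lower. The probes of phaC had log2 differences of -1.48 and -0.70, and without the cross-hybridising one phaC did not reach 2-fold. Multidrug efflux pumps were at 0.27 (10 genes, 61.1th percentile), with PP_1388 5.64-fold higher and PP_3548 3.32-fold lower. Iron acquisition was at 0.35 (5 genes, 71.3th percentile), where 1 of the kept genes was a member by symbol. PP_0119 (a FUR family regulator), which joined by a product word alone, was 5.54-fold lower, while the gene fur (PP_4730) was detected on neither array. Protein secretion was at 0.078 (9 genes, 61.3th percentile). The type VI secretion list had 0 genes on the array. With members by symbol alone, heat shock was at 4.11, RNA polymerase at 0.36, general stress at 0.096, DNA repair at 0.26, flagella at -0.37 (7.07th percentile), efflux pumps at 0.55 and protein secretion at 0.0089, and envelope stress and iron acquisition kept 2 genes and 1 gene.

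Of the 12 largest differences upward, 5 were heat shock list members. The others were PP_3808 (an MbtH domain protein, 38.9-fold higher), PP_0709 (a nucleoside transporter, 35.1-fold), PP_4705 (a glyoxalase family protein, 30.4-fold), dapB (PP_4725, next to dnaJ, 29.5-fold), mioC (a flavodoxin, 21.9-fold), PP_0104 (a cytochrome c oxidase subunit I, 16.7-fold) and mreB (a cell shape protein, 16.5-fold). The control signals of PP_3808, PP_0709 and PP_4705 were 6.40, 7.62 and 6.80, near the lowest detected signal of 6.37. Downward, PP_1628 (a CinA domain protein) had signals of 22163 and 11.4, a log2 difference of -11.89. Next were the cbb3-type cytochrome oxidase genes ccoP-1, ccoN-1 and ccoN-2, at 8.04-fold, 7.74-fold and 6.94-fold lower. They were followed by flgH, PP_1726 (an ABC transporter binding protein, 6.60-fold), nuoC, PP_4636 (an acetyl-CoA acetyltransferase, 6.34-fold), rimM (a 16S rRNA processing protein, 6.03-fold), phhA (phenylalanine 4-monooxygenase, 5.997-fold), nuoN and PP_5393 (a heavy metal transport protein, 5.79-fold). A neighbouring gene on the same strand, detected on both arrays, existed for 7 of the 12 upward genes and was at least 2-fold higher for 5. The exceptions were the largest rises, PP_3808, with a neighbour at 0.20, and PP_0709, with neighbours at -0.22 and -0.19. Such a neighbour existed for 10 of the 12 downward genes and was at least 2-fold lower for 6. A gene counted when 1 such neighbour passed, and the other neighbours of nuoC and rimM were at 0.25 and 0.18. PP_1628 counted through recA, at -1.48 against its own -11.89. Among the upward genes dnaK, dnaJ and dapB lie next to each other, so their matches are not separate.

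A further 735 genes were detected on the heat array alone and 108 on the control array alone, of which 58 and 71 had a bound of at least 2-fold. These counts depend on the scaling too, at 34 and 108 with array medians and 215 and 14 without scaling. After heat, PP_3044 (a phage portal protein) was at least 54.6-fold higher, PP_3371 (a sensor kinase) at least 28.4-fold, PP_3613 (L-sorbosone dehydrogenase) at least 26.0-fold, mgtB (a magnesium pump) at least 15.2-fold and pcaD at least 13.2-fold. In the other direction, PP_2297 (an integrase) was at least 394.8-fold lower, PP_0242 (a TetR family regulator) at least 12.7-fold, PP_3689 (a putative protein phosphatase) at least 12.02-fold, cyoE2 (a heme farnesyltransferase) at least 5.21-fold and PP_0386 (a sensory box protein) at least 5.03-fold.

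The deposited log2 folds of the authors' deposited table differed from the values computed here by -0.0052 for every gene. Spearman's rho across kept genes was 1, and 99.8% had the same sign. Both sets of values are the log2 ratio of the same signals minus a constant. This agreement was therefore fixed by construction and is not separate support.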

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

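No paired analysis was possible because each group has 1 array, and for the same reason no array was left out in turn. The normexp background correction was not run for the gene counts, the lists or the named genes, since it needs mean and background signals. Values are list medians relative to the median gene, in log2 units, unless stated. A list median was called moved when it differed from the main value by more than the probe SD of 0.756 divided by the square root of the number of genes, a technical error only. Of the list medians recomputed, 154 belong to settings that leave all relative medians as they are or shift them alike, so they test nothing. Of the other 259, 209 stayed within that and 50 moved. Only 211 of the 259 differed from the main value at all, so some that stayed are lists the setting did not change. Most settings cannot test single genes either. Without scaling all 76 named genes shift by 0.97, which exceeds the probe SD, and with array medians all shift by -0.54, which does not and took 2 genes near 0 to the other sign. Only quantile normalisation, loess and removal of the trend gave every named gene its own shift. After loess 15 of 76 moved, and after the others 0 did. The cause was not tested except where the alternative's construction shows it.

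The counts of higher and lower genes were 159 and 882 with array medians, where hslR was at -0.017 and PP_4849 at -0.39, and 813 and 48 without scaling. The lower count was 263 after loess. The counts were 703 and 951 without the filter, 422 and 772 at 1.5-fold, and 151 and 127 at 3-fold, where the construction moves them, and 687 and 536 with detection on at least 1 array.

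After loess, heat shock was at 4.17, ribosomal proteins -0.64, respiratory chain -0.82, ATP synthase -0.26, cold shock 1.21, translation factors 1.32, RNA polymerase 0.93, flagella 0.022, polyhydroxyalkanoate 0.71 and secretion 0.45. Without the filter, heat shock was at 1.87, ribosomal proteins -0.28, respiratory chain -0.34, ATP synthase -0.41, the tricarboxylic acid cycle -0.37, transposases -0.32, envelope stress -0.11, oxidative stress 0.061, cold shock 1.33, translation factors -0.46, flagella -0.00578, iron -0.092, osmoprotection 0.36, amino acids 0.27 and polyhydroxyalkanoate 0.14. With detection on at least 1 array, heat shock was at 1.61, respiratory chain -1.40, ATP synthase -1.10, the tricarboxylic acid cycle -0.91, envelope stress 0.15, oxidative stress -0.62, general stress -0.30, tRNA synthetases -0.67, RNA polymerase -0.28, amino acids -0.067, secretion -0.21 and phage-related -0.44. With genes above each array's median, heat shock was at 2.75 and amino acids at -0.0361. With members by symbol alone, heat shock was at 4.11, translation factors -0.022, flagella -0.37, efflux pumps 0.55 and osmoprotection 0.45.

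Among alternatives chosen after seeing the data, heat shock was at 0.79, RNA polymerase at -0.17 and polyhydroxyalkanoate at -0.10 in the value table of the series, which lacks the 152 brightest probes. Heat shock was at 2.89 and efflux pumps at -0.041 without cross-hybridising probes, and heat shock was at 3.61 with the trend on probe composition and signal removed. Over all settings the heat shock list ranged from 0.79 to 4.17, ribosomal proteins from -1.12 to -0.28 and the respiratory chain from -1.40 to -0.34. Of these, heat shock lay inside the middle 95% of random lists in the series value table (94.8th percentile), ribosomal proteins without the filter (2.85th), and the respiratory chain in no setting tried. Transposases and integrases, inside it in the main setting, lay outside it after quantile normalisation (1.27th percentile), after loess (1.26th), with detection on at least 1 array (0.42th) and in the series value table (2.21th), and the tricarboxylic acid cycle did so against unmatched random lists (2.24th). Signal over background limits the rest: 43.7% of probes were detected on neither array.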

Other observations

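The groups of this paragraph and the next were put together after the values were seen, although several of their genes were also named by the fixed rule or belong to fixed lists. Oxidase subunit genes went both ways. Of the cbb3-type cytochrome oxidase genes, ccoN-1, ccoP-1 and ccoN-2 were 7.74-fold, 8.04-fold and 6.94-fold lower after heat, but ccoO-1, ccoQ-1 and ccoO-2 had log2 differences of 0.55, 0.11 and -0.42. Of the cytochrome c oxidase genes at PP_0103 to PP_0106, PP_0104 was 16.7-fold and PP_0103 3.20-fold higher, and PP_0106 was at -0.15. The values of the 2 sets overlap, and no difference between them was tested. Of 21 genes of the synthesis and regulation of alginate, an exopolysaccharide, 6 were detected on both arrays, 7 on the heat array alone and 8, algD among them, on neither. Of the 6, the regulator genes algB and mucA were 11.3-fold and 7.56-fold higher and algY (a Do-type protease) 9.79-fold higher, alg44 and algE were at 0.37 and -0.75, and algL was 2.34-fold lower. Of the 7, alg8, algI, algT and algA were at least 3.57-fold, 2.41-fold, 1.73-fold and 1.20-fold higher, and the bounds of algX, algK and algZ set no direction. With array medians that of algA sets none either. The group was not compared with random lists.

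Some adjacent genes differed in the same direction and others did not. Of the kept neighbours of genes past 2-fold, 38.1% were past 2-fold in the same direction. Among all kept genes 12.3% were at least 2-fold higher and 20.0% at least 2-fold lower. Beside dnaK and dnaJ, dapB was 29.5-fold higher, while carA and carB, the next genes, had log2 differences of 0.20 and -0.40. On the other side of dnaK, grpE was detected on the control array alone, near the lowest detected signal, and without scaling its bound sets no direction. The fatty acid synthesis genes accC-1 and accB were 5.86-fold and 7.56-fold higher with aroQ1 beside them at 16.4-fold. PP_1895 and PP_1896 (ABC transporter) were 8.40-fold and 15.5-fold higher, with PP_1894 beside them at -0.075, and PP_0939 and tldD were 9.67-fold and 11.4-fold higher, with PP_0938 beside them 2.57-fold lower. The protease gene lon-2, next to clpX, was 7.80-fold higher, and hupB on its other side 1.83-fold lower. Across 592 neighbouring pairs of kept genes the log2 differences correlated with r of 0.40 and rho of 0.33. Of 163 Gene Ontology terms, protein folding (9 genes, median 2.37 relative to the median gene) and Gram-negative cell wall (5 genes, 2.80) lay above all 2000 random lists, and rRNA binding, structural constituent of ribosome and translation lay below all. Terms and fixed lists can share genes, so these are not separate results. Structural constituent of ribosome had the same size (31 genes), median and number of 2-fold lower genes (20) as the fixed ribosomal list.

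In the following tests, that of PP_3371 and that of probe composition for the ribosomal genes were chosen only after the result was seen. With undetected signals taken at face value, 4 genes differed by over 100-fold, namely PP_1628, PP_2297, PP_3044 and PP_3371. PP_1628 alone was detected on both arrays, and the bounds of the others were at least 394.8-fold, 54.6-fold and 28.4-fold. A fault of a single spot may explain PP_1628, which lay 10.4 log2 units from its neighbour recA, and PP_3044, whose bound lay at least 6.93 from PP_3043 and 7.49 from PP_3045 (median 7.21), against a 99th percentile of 5.36 over 1113 neighbouring pairs. The use of the bound for PP_3044 was chosen after its face-value distance, 9.24, had been seen, and both lie above that percentile. Genes chosen for a difference of over 100-fold lie this far from any neighbour that does not differ strongly itself. The selection therefore nearly fixed the outcome, and the distances lend no support to a spot fault. Real transcripts with their own promoters would look the same, so a spot fault stays a hypothesis. For PP_2297 and PP_3371 there were 0 detected neighbours on the same strand within 200 bp, and a spot fault and a change in the transcript cannot be told apart.

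The heat shock list stood above other genes. The tables argue only against a trend on probe composition and brightness shared by all probes as its cause. After that trend was removed the list was at 3.61 relative to the median gene. The trend was small, its removal shifting the named genes by -0.17 to 0.34, and effects of single probes were not tested. Of the list's kept genes dnaJ alone was measured by a cross-hybridising probe, and without such probes the list was at 2.89. Leaving out 1 gene could not bring the list under the bound of 1 set beforehand, so that test decides nothing. What remains is that the other kept genes were measured by probes not marked as cross-hybridising. A difference between the cultures unrelated to temperature stays open and cannot be told apart from heat with 1 array per group. The biological explanation, a response to 45 °C, is the one the design names, and it may hold, but it was not tested against replicate cultures.

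Of 53 ribosomal protein genes, 22 were not detected on both arrays. Probe composition is a candidate explanation, as their probes had a median GC content of 46.6% against 49.0% for the detected ones, a difference of 2.41 percentage points, but it need not account for many of these genes. Both medians lie between 45% and 50%, where 40.8% of all probes were detected on the control array, against 48.4% between 50% and 55%. Low transcription of these genes stays open. The test planned for it, the control signal of 14 detected ribosomal neighbours (median 147.0), decides nothing, since signals of different probes are not comparable and only detected neighbours enter it. This fault was noticed after the value, which lay above the 21.9 of all kept genes, had been seen. Sequence differences between the isolate and KT2440 stay open and cannot be told apart from the rest, since 0 genomes of the isolate were used here.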
